A study of Mus musculus with 5 samples.

How the data were processed

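CUT&RUN was done on dissociated cells of male mouse gonads, passed through a 70 µm filter, with 100000 cells per assay, per the labels. Libraries were grouped by antibody and stage from their titles and characteristics. Of 5 libraries in the series, 4 have a peak list here, and each group holds 1 library. The IgG library was not analysed here; its title and its other labels give different stages, so its stage was left open. The deposited files are peak lists with 3 columns, chromosome, start and end, in mm10 coordinates; they hold no score, fold enrichment or read count, and peaks were therefore neither ranked by strength nor filtered. The submitters' processing notes name Trim Galore 0.6.10, Bowtie2 2.5.2, MACS2 and the build mm10. The version and settings of the peak calling, and whether the IgG library served as control, are not given in the sources used here. MACS2 usually gives peaks of varying width, so whether these lists are its direct output, and what their counts and order then mean, is left open. Nearly constant peak widths within a list (150, 630, 160 and 210 bp) mean that the width carries no information on a single peak, and the 630 bp peaks at E16.5 overlap other features more readily than narrower ones. The order of peaks within a file does not follow position and is not explained in the sources used here.

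Gene coordinates came from a RefSeq table for GRCm38.p6, which shares the coordinates of mm10, with 49943 genes on the assembled chromosomes, 21887 of them protein-coding. The table gives the start and end of a gene without strand or exons, so a position within 1000 bp of either gene end replaced the promoter window that had been planned, and no intron, exon or UTR is stated. No genome sequence was used, so the planned search for the CRE motif and the matching of genes on promoter CpG content were not run. Peaks on unplaced or unlocalised scaffolds were left out of the comparisons and counted separately. Positions are printed 1-based, and distances run from the peak midpoint to the nearest gene end.

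Peaks were compared by overlap of at least 1 bp. Observed shares were set against 1000 random placements of peaks of the same widths on the same chromosomes, between the first and last annotated gene of each, without regard to assembly gaps. Fewer placements were used for the alternatives and for the shares with an H3K4 midpoint within 1000 bp. Sharing between stages was also set against 1000 draws of as many H3K4 peaks. A gene was counted with a peak when the peak overlapped the 1000 bp on either side of an end. The 20 gene lists, 13 by symbol and 7 by symbol pattern, were fixed before the data were examined, together with the comparisons, and all 283 fixed symbols were found in the table. For each list, 10000 random lists of the same size were drawn from protein-coding genes, and again from genes with an H3K4 peak at an end. A list is called above or below when fewer than 2.5% of random lists reach its count. Random placements and lists describe these libraries and are not tests between stages, and no p-value is given. Shares carry 95% Wilson intervals, which cover counting error only. The depth behind a peak list is unknown, so a peak missing from a list is not shown to be absent.

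Named are the nearest genes of the first 10 peaks of each CREB list, the 10 protein-coding genes with the best mean position among those with a peak at all 3 stages, the first 5 peaks seen in a single list, up to 6 members of each fixed list ranked by number of stages and then by best position, and 15 genes fixed in advance (Star, Cyp11a1, Cyp17a1, Hsd3b1, Nr5a1, Insl3, Lhcgr, Sox9, Amh, Ddx4, Fos, Nr4a1, Crem, Per1 and Creb1). This rule was written for scores; because the files hold none and widths tie, file order took their place. A gene that this rule selects is not reported here. Alternatives fixed in advance were gene ends of 500 and 2500 bp, protein-coding genes only, reciprocal overlap of 50%, midpoints within 200 bp, overlap of 50% of the CREB peak, CREB peaks away from gene ends, and lists drawn from H3K4 genes. Alternatives that use file order, a common width of 150 bp, or matching on H3K4 list order in 10 parts were added after seeing the data. The same holds for single-stage peaks judged by midpoints within 200 or 1000 bp. Comparisons among H3K4 genes and those with matching used only the members of a list that have an H3K4 peak.

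Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The code was tested on simulated data. In peak lists made after each CREB library, on 21887 genes, all 200 planted gene ends were recovered in each, and the excess at gene ends was estimated as 203, 179 and 202 peaks for E13.5, E16.5 and E18.5 where 200 had been planted. Of 100 random gene lists, 2, 2 and 0 were called. With simulated peaks that followed H3K4 list order on 11532 genes, 59 of 100 lists of early genes were called without matching and 1 with it. Planted peaks lay inside the window in which they were counted, and the last simulation depended only on the order used for matching. These runs therefore check the code and do not show how the methods perform on real peak lists.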

Results

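Chromatin of the mouse fetal testis was profiled by CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around a bound protein or modified histone. An antibody against CREB, the transcription factor that responds to cAMP signalling, was used at 3 stages of embryonic development, E13.5, E16.5 and E18.5 (days of gestation). An H3K4 antibody was used at E18.5; the labels name the histone residue without its methylation state. There was 1 library per antibody and stage, so no value below has a replicate check. The series also holds an IgG library, which was not analysed here. The deposited peak lists held 862 CREB peaks at E13.5, 3528 at E16.5, 2957 at E18.5 and 21211 H3K4 peaks. Nearly every peak of a list had the same width, which was 150 bp at E13.5, 630 bp at E16.5, 160 bp at E18.5 and 210 bp for H3K4, and the lists covered 129249, 2222564, 473120 and 4454310 bp. The read depth of the libraries is unknown. On the assembled chromosomes lay 834, 3526, 2947 and 21202 peaks, and these enter every comparison except that of list position, which uses all peaks.

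CREB peaks of the fetal testis lay at the ends of genes at all 3 stages. Within 1000 bp of an annotated gene end lay 85.7% of the E13.5 peaks (95% interval 83.2 to 87.9), 80.3% at E16.5 (78.9 to 81.5) and 83.5% at E18.5 (82.1 to 84.8). The share was 69.9% (69.3 to 70.5) for H3K4 peaks. Protein-coding genes accounted for most of it, with 82.5%, 75.6% and 79.8% of the CREB peaks and 63.2% of the H3K4 peaks at their ends. A further 11.3%, 14.4% and 13.1% of the CREB peaks lay inside a gene body away from such ends, and 6.24%, 10.01% and 7.16% lay outside genes. Random placements of the same widths on the same chromosomes put 7.14%, 8.34% and 7.09% of CREB peaks at a gene end, so the observed shares were 12.0, 9.62 and 11.8 times higher, and none of 1000 placements reached them. The H3K4 share was 9.96 times its random value of 7.01%. After a shift of every peak by 10 kb up and down, which leaves it near the same genes, 16.1% and 13.9% lay at a gene end at E13.5, 16.1% and 16.8% at E16.5, 14.4% and 14.8% at E18.5, and 12.5% and 12.9% for H3K4. The annotation used gives gene starts and ends without strand, so a gene end stands here for a promoter or a 3' end. It gives only the outer ends of a gene, so a start site inside a gene is not counted as a gene end.

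The genes with the earliest list positions at all 3 stages were Oaz1, Cep57, Fam76b, Opa3, Dact3, Xab2, Pet100, Csnk1g2, Foxred1 and Srpr. Oaz1, which encodes an antizyme that restrains polyamine synthesis, had a CREB peak at chromosome 10, 80826338 to 80826497 (mm10), in position 1 at E18.5, 3 at E13.5 and 6 at E16.5. Its midpoint lay 238 bp outside the gene end. A single peak at chromosome 9, 13827465 to 13827624, lay within 1000 bp of both Cep57 and Fam76b, which overlap, and stood in positions 5, 1 and 2 at E13.5, E16.5 and E18.5. The peak between Xab2 and Pet100 on chromosome 8 stood in positions 7, 8 and 12, and the one at Foxred1 and Srpr on chromosome 9 in positions 6, 30 and 8. Opa3, which encodes a mitochondrial protein, stood in positions 8, 2 and 5, Dact3 in 4, 28 and 3, and Csnk1g2, a casein kinase gene, in 10, 4 and 13. Other genes nearest to a peak among the first 10 of a list were Nbr1, Gm20783, Ctdnep1, Ppm1b and Pmvk at E16.5 and Hsd17b12, Tpst2, Nbr1, Sp1 and Ss18l2 at E18.5, and each of these peaks overlapped one at both other stages. The Pmvk peak, at chromosome 3, 89458593 to 89459222, lay inside this gene of the mevalonate pathway, 4367 bp from its nearest end. Of the first 10 peaks at E13.5, 3 lay on unplaced scaffolds. No source used here says that list order follows peak strength, and the order is used below only as it stands in the files.

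CREB peaks found at E13.5 were nearly all found again later. Of the E13.5 peaks, 94.5% (92.7 to 95.8; 788 of 834) overlapped an E16.5 peak and 92.2% (90.2 to 93.8; 769) an E18.5 peak. In the other direction 22.1% (20.7 to 23.5) of E16.5 peaks and 26.1% (24.5 to 27.7) of E18.5 peaks overlapped an E13.5 peak. E16.5 and E18.5 shared more, with 67.1% (65.5 to 68.6) of E16.5 peaks in the E18.5 list and 81.3% (79.8 to 82.6) of E18.5 peaks in the E16.5 list. Shares that involve E16.5 depend on its 630 bp width. With every peak set to 150 bp, 84.9% of E13.5 peaks overlapped an E16.5 peak and 92.1% an E18.5 peak. At that width 59.6% of E16.5 peaks were in the E18.5 list and 71.4% of E18.5 peaks in the E16.5 list. In the E13.5 list were then 20.1% of E16.5 peaks and 26.1% of E18.5 peaks. The Per1 and Fos gene ends were among the places with a peak at every stage. Merging the 3 lists gave 4092 regions, of which 772 held a peak of every stage, 1595 held E16.5 and E18.5 only, 24 held E13.5 and E18.5 only and 9 held E13.5 and E16.5 only. Random draws of as many H3K4 peaks overlapped in 16.8% (E13.5 in E16.5), 13.9% (E13.5 in E18.5), 3.98% (E16.5 in E13.5), 14.0% (E16.5 in E18.5), 3.94% (E18.5 in E13.5) and 16.7% (E18.5 in E16.5) of cases, and random placements in at most 0.125% on average. When as many first peaks were taken from each list as E13.5 holds, the shares moved to between 68.7% and 73.6% in all 6 directions.

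**Figure D1:**
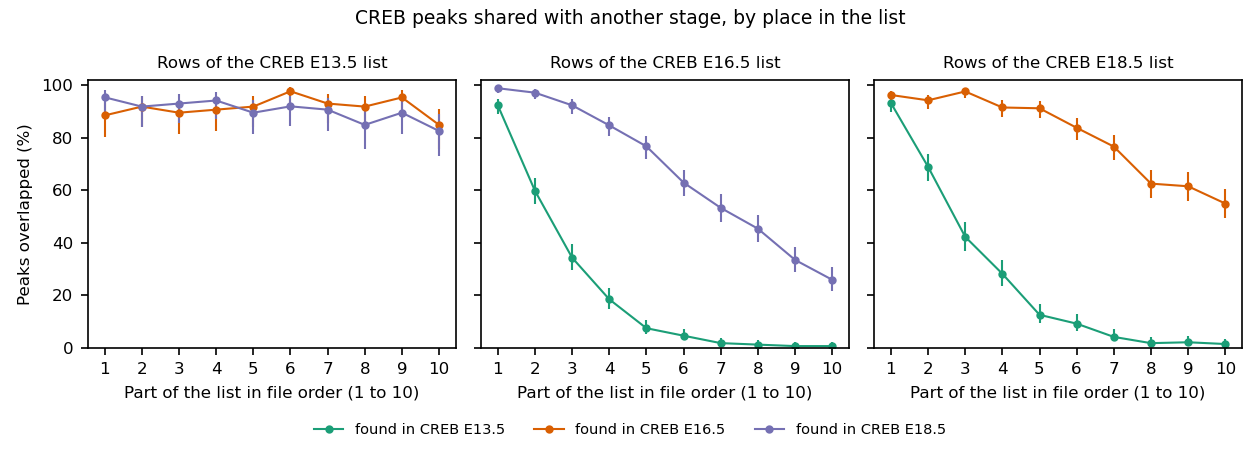
Share of CREB peaks (%, y axis) overlapped by a peak of another stage, for 10 successive parts of each list in file order (x axis), with points for 1 library each and bars for 95% Wilson intervals. In the E16.5 list the share found at E13.5 runs from 92.4% in the first part to 0.568% in the last.

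List position and sharing went together in the E16.5 and E18.5 lists, whereas across 10 successive parts of the E13.5 list the share stayed between 84.9% and 97.7% for E16.5 and between 82.6% and 95.4% for E18.5. Of the first 862 peaks at E16.5, 70.2% (67.0 to 73.1) overlapped an E13.5 peak, against 6.53% (5.65 to 7.53) of the later ones, and at E18.5 these shares were 68.8% (65.6 to 71.8) and 8.88% (7.73 to 10.2). Across peaks with midpoints within 200 bp of each other, positions in the lists had a Spearman correlation of 0.678 for E13.5 and E16.5 (741 peaks), 0.667 for E13.5 and E18.5 (782) and 0.727 for E16.5 and E18.5 (2203). These are correlations across peaks, which are not independent replicates.

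Peaks listed at a single stage numbered 19 at E13.5, 1150 at E16.5 and 523 at E18.5. The peak at Egr1, an immediate early gene, was in position 14 at E18.5 (chromosome 18, 34860887 to 34861046, 240 bp from the gene end), and the nearest CREB peak of another list was 71019 bp away. For E16.5 peaks at Rel and Tead1 the nearest CREB peak of another list was 105186 and 834608 bp away, and for an E18.5 peak at Tmem60 it was 1668059 bp away. Several others lay close to a peak of another stage without touching it, with midpoints 433 bp apart at H3c1, 467 bp at Crlf2 and 479 bp at Akt1s1 for E16.5, and 437 bp at Tnrc6c and 397 bp at Pcnx3 for E18.5. Sin3a had an E18.5 peak inside its gene body, 2433 bp from the nearest peak of another stage. Positions 1 and 2 of the E13.5 list are scaffold peaks listed at that stage alone. Among the first 5 such peaks on the assembled chromosomes, in positions 219 to 557 of 862, those nearest to Crlf2, Gm20783 and Abhd11 lay 468, 830 and 470 bp from a peak of another stage, and those nearest to Cdh8 and Slc39a11 lay 141910 and 130586 bp from the gene. Single-stage peaks were at a protein-coding gene end in 59.4% of cases at E16.5 (56.5 to 62.2), against 85.1% (82.4 to 87.5) for E16.5 peaks shared by all stages. At E18.5 the shares were 68.8% (64.7 to 72.7) and 84.5% (81.7 to 86.9), and at E13.5 they were 10.5% (2.94 to 31.4; 2 of 19) and 84.2% (81.4 to 86.7). Judged by midpoints within 200 bp, 30 peaks were seen at E13.5 alone, 40% of them at a gene end. With no other CREB midpoint within 1000 bp, 16 were seen at E13.5 alone, 6.25% of them at a gene end. Median list percentiles of the single-stage peaks were 85, 75.9 and 78.5, near the end of each list.

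H3K4 peaks lay next to most CREB peaks. An H3K4 midpoint lay within 1000 bp of 90.9% of E13.5 peaks (88.7 to 92.7), 85.9% of E16.5 peaks (84.7 to 87.0) and 88.3% of E18.5 peaks (87.1 to 89.4), against 1.59%, 1.58% and 1.54% for random placements. H3K4 midpoints stood on both sides within that distance at 31.2%, 24.6% and 25% of the CREB peaks. At Fos, the immediate early gene, the E18.5 CREB peak (chromosome 12, 85473645 to 85473804) lay inside an H3K4 peak (85473612 to 85473821), whereas at Per1, a clock gene, the nearest H3K4 peak (chromosome 11, 69095555 to 69095764) lay inside the gene and did not touch the CREB peak (69094967 to 69095126). Direct overlap by at least 1 bp was found for 32.1% (29.1 to 35.4), 66.8% (65.2 to 68.3) and 33.1% (31.4 to 34.8) of CREB peaks at E13.5, E16.5 and E18.5, which is 105, 93.1 and 103 times the random share. With every peak set to 150 bp the E16.5 share was 32.3% (30.8 to 33.9), beside 32.1% and 32.2% at the other stages. Away from gene ends, 68.9% (60.1 to 76.5), 58.6% (54.9 to 62.2) and 64.5% (60.1 to 68.6) of CREB peaks had an H3K4 midpoint within 1000 bp. Seen from the H3K4 list, 5.03%, 19.6% and 16.6% of its peaks had a CREB midpoint within 1000 bp at E13.5, E16.5 and E18.5. Only the E18.5 CREB library matches the H3K4 library in stage.

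**Figure D2:**
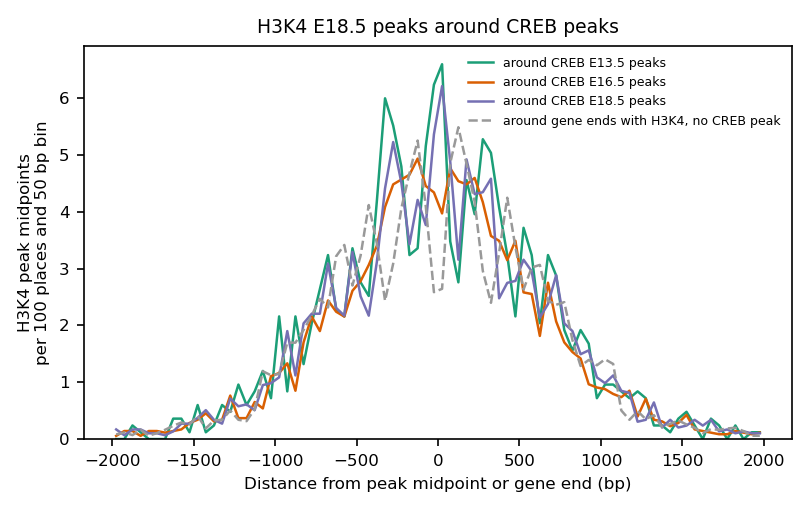
H3K4 peak midpoints per 100 places and 50 bp bin (y axis) by distance in bp (x axis) from CREB peak midpoints of each stage, and from gene ends with an H3K4 peak and no CREB peak (dashed). Each line is 1 library; between 0 and 100 bp the mean is 5.37 around E13.5 peaks, 4.38 around E16.5 peaks, 5.06 around E18.5 peaks and 3.54 around the gene ends without CREB, and between 100 and 200 bp it is 3.48, 4.65, 3.93 and 5.06 in the same order.

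At the gene level, 861 of 21887 protein-coding genes had a CREB peak within 1000 bp of an end at E13.5, 3271 at E16.5 and 2817 at E18.5, and 11532 had an H3K4 peak there. Oaz1, Per1 and Fos belonged to the 838 genes with a CREB peak at all 3 stages. Crem and Creb1, which encode CREB family members, belonged to the 1618 genes with a peak at 2 stages, in both cases E16.5 and E18.5. A peak at 1 stage was found for 1199 genes, Egr1 among them. H3K4 peaks were present at 96.3% (94.8 to 97.4), 95% (94.2 to 95.7) and 95.8% (95 to 96.5) of the genes with CREB at E13.5, E16.5 and E18.5, against 52.7% of all protein-coding genes. E13.5 shared 846 genes with E16.5 and 852 with E18.5, and E16.5 shared 2434 with E18.5, where independent lists would share 129, 111 and 421. Among genes with H3K4 the shared numbers were 816, 820 and 2337 against 223, 194 and 727. In genes over 5 kb long with CREB at 1 end and H3K4 at 1 end, the ends were the same in 653 of 654 genes at E13.5, 2476 of 2507 at E16.5 and 2146 of 2160 at E18.5.

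Genes of cholesterol synthesis and uptake, the pathway that supplies the steroid precursor, had the highest share of members with a CREB peak among the 13 lists fixed by symbol at E16.5 and E18.5. Of 24 genes, 6 had a peak at E13.5, 13 at E16.5 and 15 at E18.5, where random lists of protein-coding genes averaged 0.947, 3.59 and 3.11. Idi1, Srebf2, Hsd17b7, Hmgcs1 and Dhcr7 were among those with a peak at every stage. At Idi1, an isomerase gene of the pathway, the peak midpoints lay 86, 79 and 74 bp from the gene end at E13.5, E16.5 and E18.5, and at Srebf2, which encodes a sterol-responsive transcription factor, 246, 182 and 261 bp. Of 10000 random lists, 3 held as many genes with a peak as this list at E13.5 and none did at E16.5 or E18.5. Among the 22 members with an H3K4 peak the counts were 6, 13 and 15 against 1.59, 5.93 and 5.11 in random H3K4 genes. The ratios to random, 6.34, 3.62 and 4.82, were 3.01, 1.79 and 2.35 with matching on H3K4 list order and 8.53 and 7.77 at E16.5 and E18.5 with as many first peaks as E13.5 holds, all above the random range.

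Known cAMP-induced CREB targets had 7, 11 and 13 of 34 members with a peak, against 1.35, 5.08 and 4.34 in random lists. Fos, Per1, Ccna2, Dusp1, Ier2 and Sik1 had one at every stage. Fos stood in positions 86, 70 and 22 of the lists at E13.5, E16.5 and E18.5, and Per1 in 29, 56 and 44. Of 10000 random lists, 5, 96 and 4 reached these counts, and the ratios of 2.16 and 2.996 at E16.5 and E18.5 were 4.02 and 5.55 with the first peaks. Nr4a1, an orphan nuclear receptor gene, had no peak at either end, with the nearest midpoint 7465, 4927 and 7466 bp from an end, and 3 CREB peaks in its gene body summed over the lists. Because a start site inside the gene would not be counted, a lack of CREB at an Nr4a1 promoter is not shown. The list of CREB family, coactivator and PKA genes was inside the random range, with 1, 7 and 4 of 25 members against 0.993, 3.73 and 3.21. It stayed inside the range among H3K4 genes (ratios 0.607, 1.13 and 0.740), with matching (0.582, 1.10 and 0.725) and, at E18.5, with the first peaks (2.77). Its members with a peak included Prkar1b at every stage, Crem, Prkaca and Creb1 at E16.5 and E18.5, and Pde8a and Crebbp at E16.5.

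The unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, had 5, 10 and 11 of 20 genes with a peak against 0.801, 3.01 and 2.56 in random lists. Eif2ak3, Hsp90b1, Ppp1r15a, Dnajb9 and Hspa5 had a peak at every stage and Xbp1 at E16.5 and E18.5. Random lists reached these counts in 11, 2 and none of 10000 draws. With as many first peaks as E13.5 holds, the E18.5 ratio to random was 3.48 and inside the random range. The ratios as reported, 6.24, 3.33 and 4.29, were 4.05, 2.18 and 2.79 among H3K4 genes and 3.60, 1.93 and 2.46 with matching on H3K4 list order, all above the range. Circadian clock genes had 3, 9 and 8 of 17 members with a peak against 0.667, 2.54 and 2.20, with Per1, Nr1d2 and Cry2 at every stage and Dbp, Per2 and Hlf at E16.5 and E18.5. The E16.5 and E18.5 counts were above the central 95% of random lists and the E13.5 count was not (257 of 10000 reached it), though with matching it was (ratio 4.87, 206 of 10000). Among H3K4 genes the later ratios moved from 3.55 and 3.64 to 2.27 and 2.29, above the range. With the first peaks only, the clock ratios of 4.05 and 4.15 were inside the range. Cell cycle genes had 2, 13 and 9 of 28 members against 1.10, 4.17 and 3.60, above the range at E16.5 and E18.5, with Ccna2 and Pcna at every stage and Mcm4, Mcm5, Aurkb and E2f1 at the later stages. The E16.5 ratio of 3.12 was 1.94 among H3K4 genes and 1.75 with matching, above the range, and 3.3 with the first peaks, inside it. At E18.5 it was inside the range among H3K4 genes (1.48), with matching on H3K4 list order (1.34) and with the first peaks (3.32). Among genes with a peak, Per1 and Per2 belong to both the cAMP target and clock lists, Ccna2 to the cAMP target and cell cycle lists, Crem to the cAMP target and CREB family lists, and Eif2ak3 to the unfolded protein response and translation initiation lists, so these lists are not independent.

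**Figure D3:**
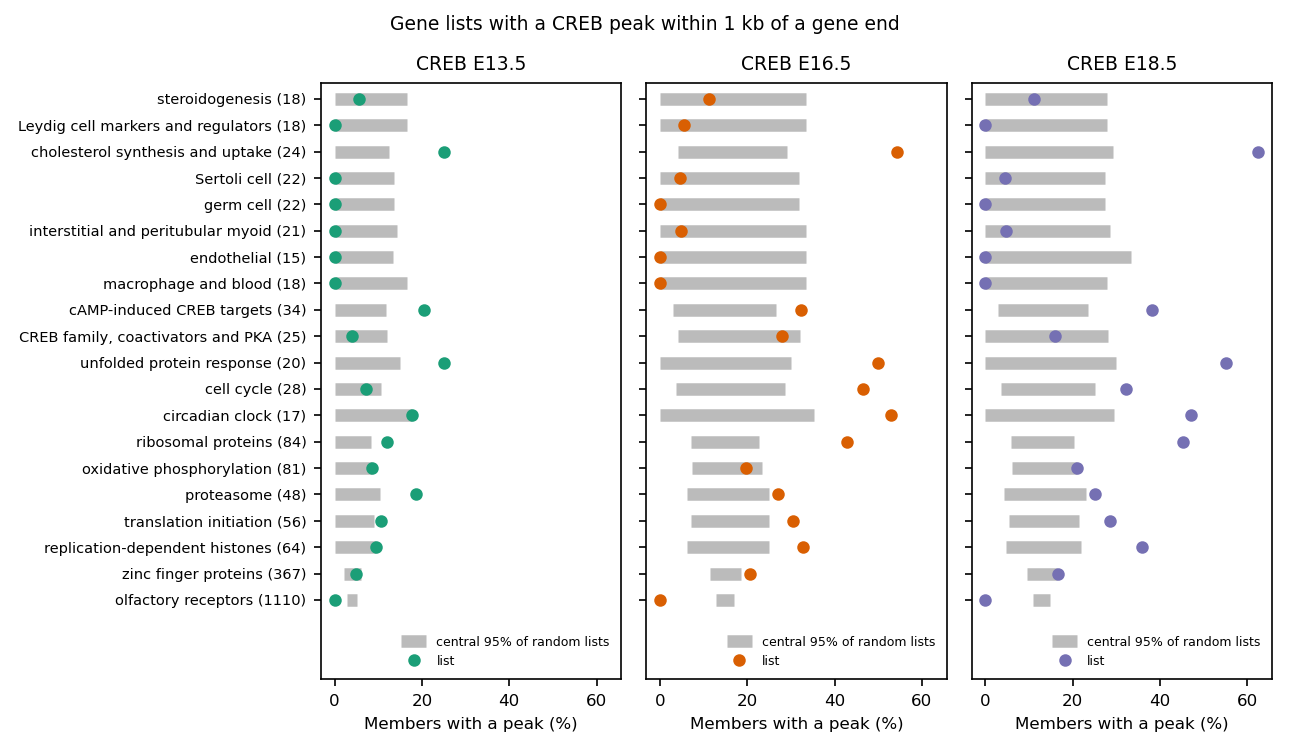
Share of each list's members (%, x axis) with a CREB peak within 1 kb of a gene end at E13.5, E16.5 and E18.5 (1 library each; list sizes in parentheses). Points are the lists and grey bars the central 95% of 10000 random lists of protein-coding genes; cholesterol synthesis and uptake reaches 62.5% at E18.5, and no olfactory receptor gene has a peak.

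Ribosomal protein genes carried peaks in 10, 36 and 38 of 84 cases against 3.31, 12.5 and 10.8 in random lists, with Rpl13a, Rpl41, Rpl4, Rpl10, Rps29 and Rps9 at every stage. All 3 counts were above the random range; the E13.5 count was inside it among H3K4 genes (ratio 1.86) and with matching on H3K4 list order (1.57). At E16.5 and E18.5 the ratios of 2.87 and 3.51 were 1.78 and 2.16 among H3K4 genes and 1.52 and 1.83 with matching, and 4.42 at E16.5 with the first peaks, all above the range. Replication-dependent histone genes had 6, 21 and 23 of 64 members against 2.51, 9.55 and 8.23, above the range at E16.5 and E18.5. A single E18.5 peak on chromosome 13, 22043035 to 22043194, lay between H2ac11 and H2bc11, and H4c1 and H3c1, as well as H2bc9 and H3c7, likewise shared a peak, so neighbouring histone genes are not separate observations. At E13.5 the histone count was above the range with gene ends widened to 2500 bp (ratio 2.81) and with matching on H3K4 list order (3.53). The matched call rests on 4 genes that share peaks in pairs. H2ac11 and H2bc11 share the E13.5 peak in position 296, and H2bc9 and H3c7 that in position 601. Random lists count neighbouring genes as separate, so neither E13.5 call shows an enrichment of histone genes. At the later stages the ratios were 2.20 and 2.79 for all 64 genes, and 5.02 at E16.5 with the first peaks. With matching, 18 and 17 of the 23 members with an H3K4 peak had a CREB peak, ratios of 3.72 and 4.251. The list had fewer H3K4 peaks than random lists (23 against 33.7). The matched ratios describe that subset and not the whole list. Proteasome genes had 9, 13 and 12 of 48 members against 1.89, 7.18 and 6.16, with Psmd3, Psmb9, Psme2, Psme3, Psmd5 and Psmb8 at every stage. These counts were above the range, but at E16.5 the ratio was 1.11 among H3K4 genes, 1.64 with the wider gene ends and 0.871 with matching, and at E18.5 it was 1.28 among H3K4 genes and 0.978 with matching, all inside the range. The E13.5 ratio of 4.76 was 3.14 among H3K4 genes and 2.33 with matching, and with the first peaks the later ratios were 3.34 and 3.87, all above the range.

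Translation initiation genes had 6, 17 and 16 of 56 members with a peak against 2.22, 8.36 and 7.25, above the range at each stage, with Eif4a1, Eif5a, Eif2ak3, Eif1, Eif4ebp2 and Eif4g1 at every stage. Among H3K4 genes the ratios were 1.57, 1.19 and 1.29, with matching 1.35, 1.03 and 1.11, and with the wider gene ends 2.40 at E13.5, all inside the range. Oxidative phosphorylation genes were inside the range with 7, 16 and 17 of 81 members against 3.20, 12.1 and 10.4, Ndufa11, Ndufb2, Atp5b, Ndufb5, Uqcrq and Ndufa2 among them. The E18.5 count was above it with the wider gene ends (1.64) and with the first peaks (2.30), and with matching the ratios were 1.14, 0.723 and 0.870, inside the range. Zinc finger genes named Zfp had 18, 76 and 61 of 367 members against 14.4, 54.7 and 47.2, above the range at E16.5 and E18.5 and inside it at E13.5 (ratio 1.25, and 0.742 with matching), with Zfp869, Zfp672, Zfp963, Zfp953, Zfp473 and Zfp367 at every stage. Among H3K4 genes the E16.5 and E18.5 ratios were 1.02 and 0.954, with matching 0.856 and 0.787, and with the first peaks 1.51 and 1.02, all inside the range except the matched E18.5 count, which lay below it. None of the 1110 olfactory receptor genes had a CREB peak, against 43.7, 166 and 143 in random lists, and 3 had an H3K4 peak, too few to compare among H3K4 genes.

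Marker genes of the testis cell types seldom had a CREB peak at a gene end. Star, Cyp11a1, Cyp17a1 and Hsd3b1, which act in androgen synthesis, had none at any stage, and neither did the Leydig cell genes Insl3, Lhcgr and Nr5a1, the Sertoli cell genes Sox9 and Amh or the germ cell gene Ddx4. The nearest E18.5 CREB midpoint was 160783 bp from an end of Star, 11175 bp from Cyp11a1, 6747 bp from Amh and 212061 bp from Nr5a1, and 1 CREB peak lay in the gene body of Cyp11a1. A start site inside that gene would not be counted as a gene end. H3K4 peaks were present at an end of Star, Cyp11a1, Nr5a1, Lhcgr, Sox9, Amh and Nr4a1 and absent at Cyp17a1, Hsd3b1, Insl3 and Ddx4. In the steroidogenesis list 1, 2 and 2 of 18 genes had a CREB peak, Fdxr at every stage and Srd5a1 at E16.5 and E18.5, against 0.717, 2.70 and 2.30 in random lists. Leydig cell markers and regulators had 0, 1 and 0 of 18 (Gli1), Sertoli cell genes 0, 1 and 1 of 22 (Ctsl), and interstitial and peritubular myoid genes 0, 1 and 1 of 21 (Maf). Germ cell genes (22), endothelial genes (15) and macrophage and blood genes (18) had none at any stage. Each of these lists was inside the central 95% of random lists at every stage, but lists this small could not be called below. Even the germ cell list at E16.5, with 0 members, had 275 of 10000 random lists as low. Pooled, the 134 markers had 5 genes with a peak at E16.5 against 20.1 in random lists, and 4 at E18.5 against 17.3. At both stages 0 of 10000 random lists were as low. At E13.5 it was 1 gene against 5.25, with 307 lists as low, inside the range. Matched on H3K4 list order, the later counts were inside the range, with 323 and 324 of 10000 lists as low. This pooled comparison was chosen after the data were seen. With the first peaks the ratio to random moved from 0.741 and 0.869 to 1.28 and 2.58 for steroidogenesis at E16.5 and E18.5, from 0.374 to 1.28 for Leydig genes and from 0.318 to 1.10 for interstitial genes at E16.5, still inside the range. The germ cell list and the macrophage and blood list had fewer H3K4 peaks than random lists, with 3 of 22 against 11.6 and 4 of 18 against 9.49.

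**Figure D4:**
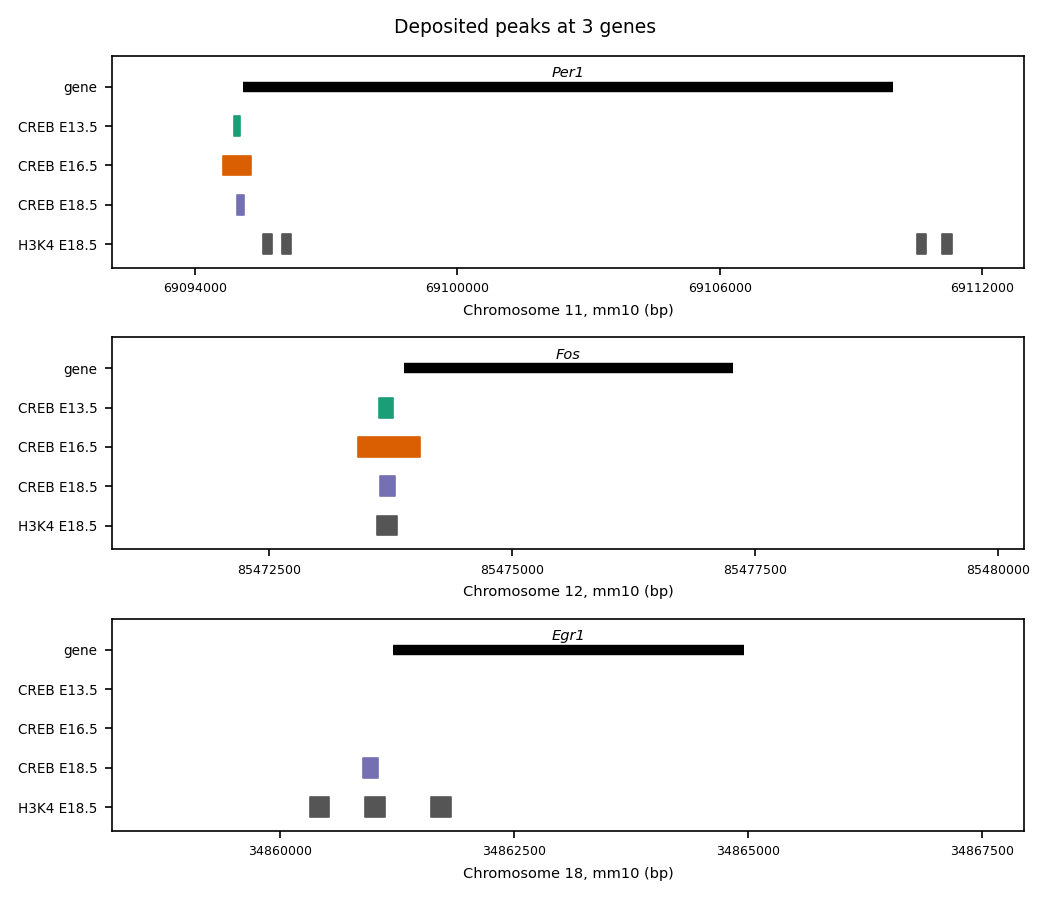
Deposited peaks (coloured boxes, 1 row per library) around Per1, Fos and Egr1, drawn to scale with the gene body in black (x axis, mm10 position in bp). Per1 and Fos have a CREB peak at an end at all 3 stages, and Egr1 has 1 CREB peak, at E18.5, in the 3000 bp on either side and the gene itself.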

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

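All tests in this part were chosen after the result was seen, except that of marker genes against genes matched on H3K4 list order, which was written before its own result but after the pattern had been noticed. Outside the assembled chromosomes, where no comparison was made and no control library was analysed, lay 28 CREB peaks at E13.5, 10 at E18.5 and 9 H3K4 peaks, and 2 CREB peaks at E16.5. Lists with more than 3 such peaks were flagged. No expected number was computed, so this limit does not show an excess in any list. Of the 28 scaffold peaks at E13.5, 1 was overlapped at E16.5, 10 at E18.5 and 1 by H3K4.

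The E13.5 CREB list is shorter than the later lists. Of its peaks, 2.28% (1.46 to 3.53) had no overlap in either later list, and 4.29% (3.13 to 5.86) with scaffold peaks included, which argues against a mostly different set of sites at E13.5 as the reason. Peaks of the later lists found at E13.5 sat early in those lists, at median percentiles of 12.7 (E16.5) and 15.2 (E18.5) against 60.7 and 62.3 for the rest, as fewer reads or a stricter limit at E13.5 could give if file order follows strength. The number of peaks at E18.5 was 0.836 of that at E16.5, so the lists did not lengthen at every step. With 1 library per stage and unknown depth, a gain of CREB sites with age cannot be told apart from a difference in depth or calling.

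CREB peaks at E16.5 overlapped H3K4 peaks in 66.8% of cases, against 32.1% at E13.5 and 33.1% at E18.5. At a common width of 150 bp the E16.5 share was 32.3%, inside the intervals of both other stages, so the 630 bp width may account for the difference. No biological explanation was tested.

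Marker genes of testis cell types (134 genes in 7 lists) had a CREB peak in 4 cases at E18.5 against 17.3 in random lists, in 5 at E16.5 against 20.1, and in 1 at E13.5 against 5.25, where 307 of 10000 lists were as low, inside the central range. At E18.5 missing H3K4 peaks are not the whole cause, since among the 55 markers with H3K4 the count was 3 against 12.9, and only 3 of 10000 random lists of H3K4 genes were as low (3 at E16.5, but 841 at E13.5). The H3K4 peaks of these markers stood late in their list (median position 13916 against 7144 for all genes with H3K4), and matched on that order 324 of 10000 lists were as low at E18.5, with a mean of 7.57 and a central range of 3 to 12. The count is thus at the lower edge of that range, and, only if file order follows strength, weak H3K4 signal from a minority of the mixed cells may explain the scarcity. A true lack of CREB at these genes was not tested and stays open.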

How the results depend on the processing

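No paired analysis was possible because each group holds 1 library. Alternatives based on file order, on the 150 bp width and on matching by H3K4 list order were chosen after the data were seen. So were the single-stage classes by midpoints within 200 bp or 1000 bp. Of the alternative values for the main results, 86 kept their label and 9 moved. A ratio to random keeps it by staying above random, whatever its size, a count within 1.5 times, and the gene end share of single-stage peaks within its interval. Some alternatives could hardly change a value. Taking as many first peaks as E13.5 holds leaves the E13.5 list whole, and 859 of its 862 peaks already had a width of 150 bp. The 86 include such values. In the alternatives, peaks at gene ends stayed between 5.4 and 22.6 times random placements, sharing between stages between 1173 and 5147 times (635 to 2216 as reported), and overlap with H3K4 between 65.2 and 117.8 times. The sharing ratios divide by very small random shares, at most 0.125% on average as reported. Their size therefore depends on peak width and list length and is imprecise. With the first 50% of each list, 428, 1857 and 1558 genes had a CREB peak at E13.5, E16.5 and E18.5, and with as many first peaks as E13.5 holds, 954 at E16.5 and 939 at E18.5; fewer peaks enter by construction. Lists above random at E18.5 numbered 6 among H3K4 genes and 6 with matching on H3K4 list order, against 10. Peaks at E13.5 alone numbered 30 with midpoints within 200 bp, 40% of them at a gene end, and the cause was not tested. With no other CREB midpoint within 1000 bp they numbered 16, with 6.25% at a gene end. Among lists above random as reported, the ratios that turned below 1 were those of proteasome genes with matching (0.871 at E16.5, 0.978 at E18.5) and of zinc finger genes with matching (0.856 at E16.5, 0.787 at E18.5) and among H3K4 genes at E18.5 (0.954); the cause was not tested. Lists inside the random range as reported also crossed 1, among them oxidative phosphorylation (0.723 at E16.5) and CREB family genes (0.725 at E18.5) with matching. For single lists, 202 alternatives left the call as it was, wherever the ratio moved, 5 gained a call, and a call ended in 28 others besides the 5 whose ratio turned below 1. Not run were the CRE motif alternatives and CpG matching (no sequence), alternatives by score (no score), and, for the 630 bp E16.5 peaks, reciprocal overlap and overlap of 50% of the CREB peak; single-stage classes by reciprocal overlap were not run either. Unknown depth limits every count of peaks missing from a list.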

Other observations

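The test of independent gene ends in this part was chosen after the result was seen; the tests of close ends and of H3K4 order were written before theirs, after the pattern had been noticed in the first peaks. Among 408 tRNA genes, which RNA polymerase III transcribes, 3 had a CREB peak within 1000 bp of an end at E13.5 (0.735%, 0.250 to 2.14), 48 at E16.5 (11.8%, 8.99 to 15.3) and 25 at E18.5 (6.13%, 4.18 to 8.89), and 163 had an H3K4 peak. With 150 bp peaks the E16.5 number was 46. Neighbouring tRNA genes can share a peak, so these genes are not separate observations. Long noncoding RNA genes had a CREB peak in 116, 502 and 400 of 12727 cases, and pseudogenes in 2, 22 and 11 of 9944. Of protein-coding genes, 3.93%, 14.9% and 12.9% had one at E13.5, E16.5 and E18.5. These shares were higher than those of tRNA genes, long noncoding RNA genes and pseudogenes at each stage. At E16.5 the protein-coding share lay inside the tRNA interval. The X chromosome held 2.16% (1.37 to 3.39), 2.78% (2.29 to 3.38) and 2.31% (1.82 to 2.91) of the CREB peaks at E13.5, E16.5 and E18.5 and 3.49% (3.25 to 3.74) of the H3K4 peaks, beside 4.41% of protein-coding genes. The gonads were male and the copy number of the X chromosome was not taken into account, so a lack of CREB there is not shown.

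Several early CREB peaks lay where the ends of neighbouring genes are close together, as at Xab2 and Pet100 or Foxred1 and Srpr. Of 1906 H3K4 peaks with an end of 2 or more protein-coding genes within 1 kb, 37.2% (35.1 to 39.4) had a CREB E18.5 midpoint within 1 kb, against 20.2% (19.5 to 21.0) of 11065 with 1 such gene. Weighted to the same H3K4 list order, the share with 1 gene was 24.4%, below the interval of the close ends, which argues against H3K4 order as the whole cause. If each gene end had on its own the share of single ends in its part of the H3K4 list, 42.7% would be expected. The 37.2% found lay below this, but the expectation may be too high. Of H3K4 peaks with no such gene end, 6.94% had a CREB E18.5 midpoint within 1 kb, and the expectation counts such a share once per end. One CREB peak can also count for several H3K4 peaks, which the interval ignores. Having more ends to reach may account for the higher share, but how much of it is not settled. These values do not show a preference of CREB for close ends beyond the number of ends. Whether there is a preference cannot be decided here, since the annotation gives no strand and some ends are not promoters, and CpG content was not analysed here.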
